A study of Pimephales promelas with 16 samples.

How the data were processed

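RNA was extracted from livers of male fathead minnows, exposed to EE2 or not, and 100 ng of total RNA per sample was labelled with Cy3 by a low-input amplification kit, per the labels' protocols. Per the same protocols 600 ng of labelled cRNA was hybridised to an Agilent 8x60k array in a single colour. The files used were the scanner output of 16 arrays and a table of processed values for the series. The scanner output holds spot intensity values on a linear scale, made with Agilent Feature Extraction 11.5.1.1, per the file headers, with background-subtracted processed signals beside median and background signals. Each array had 62372 spots, of which 61053 were non-control spots of 49849 probes, 41517 with 1 spot, 7973 with 2 and 359 with 10. The deposited value table holds log2 values of 25960 probes, 17 of them control probes, centred so that each probe's median over the arrays is 0. Its column medians were 0.0033, 0.0085, 0.0096 (repeat array), 0.0089, 0.029, 0.029 (repeat array), 0.011 and -0.0034 for controls 1, 3, 3, 8, 9, 9, 13 and 14, and -0.0065, -0.018, -0.034, -0.013, -0.014, -0.015, -0.0074 and -0.0052 for EE2 replicates 5, 6, 10, 11, 12, 16, 17 and 18. Set against the scanner values, it matched a quantile normalization of the processed signals centred by probe, with a median absolute difference of 0.00113 on the log2 scale and a correlation of 1 in each column across probes, against 0.0459 for scaling on the 75th percentile. Its scale, centring and direction are thereby known from the data, and its choice of probes is not given in the sources used here.

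Groups were read from the sample titles. Arrays titled as repeats of controls 3 and 9 were averaged with the array of the same number after normalization, giving 6 control and 8 EE2 livers, although the series text counts 8 replicates per group. The groups share no replicate numbers. Each slide held 8 arrays, 4 of each group.

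From the scanner files, log2 of the processed signal was averaged over the spots of a probe, leaving out control spots and spots marked as non-uniform or population outliers, which left 189 missing values. Each array's 75th percentile over non-control probes was subtracted. A probe was tested if it was well above background in at least 6 of the 14 livers, on every array of the liver. Groups were compared with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, two-sided, Benjamini-Hochberg adjustment, threshold 0.05). Slides were compared on 16 arrays with group as a term and the liver as a random block (duplicateCorrelation), on the 23254 tested probes with a value on every array. Array measures were averaged per liver and compared by exact permutation over all 3003 splits. Spread between arrays was the SD of log2 differences over tested probes. Spike-in scaling used the mean of 7 spike-in probes well above background on all arrays. Figures were drawn with matplotlib 3.10.9.

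Before the data were examined it was fixed that vitellogenin, oestrogen receptors and members of 28 gene lists would be named where the files carry gene names, and that a probe without a name would be given by ID only among the 3 largest rises or falls. No table pairing the probes with genes was used here, so 0 probes were named by gene, the lists were not tested, and the IDs of 2 rises and 2 falls are given. The largest rise and fall were taken among probes with adjusted p under 0.05.

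The fits were tested on simulated data with the real probes' means and spreads, 23268 probes and 200 of them changed. For EE2 against control, 0% of 50 probes changed by 0.5 on the log2 scale were called, 32% of 50 changed by 1, 72% of 50 changed by 2 and 98% of 50 changed by 4, with 7 unchanged probes among 108 calls. For the slide fit the shares were 12%, 64%, 96% and 100%, with 27 unchanged probes among 163 calls, above the intended rate. In the real EE2 comparison 25.8% of tested probes changed, so the adjusted threshold was less strict there than in the simulation. The simulated slide data also had a lower correlation between arrays of a liver than the 0.961 estimated from the real arrays. These shares therefore do not give the sensitivity of the real fits.

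Alternatives planned beforehand were quantile, median and spike-in scaling, the deposited table, other filters on dim probes, other treatments of the repeat arrays, slide as a term and each slide alone, other variance models, thresholds, and leaving out each liver. A normexp correction had been planned on mean spot signals. That column is not used here, and the correction was run on median signals instead (offset 50).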

Results

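Livers of male fathead minnows (Pimephales promelas, a small freshwater fish used in toxicity testing) were profiled on single-colour microarrays. The exposed males had been held for 96 h in 25 ng/L EE2, which is 17alpha-ethinylestradiol, the synthetic oestrogen of contraceptive pills, and the other males were controls. The title of the series places it in a comparison of laboratories, of which these arrays are the share of 1 laboratory. There were 16 arrays on 2 slides, with 8 control and 8 EE2 arrays. The titles of 2 control arrays repeat the sample number of another array, so the 8 control arrays were taken as 6 livers, while the 8 EE2 arrays were 8 livers. The series text instead counts 8 biological replicates in each group. Each array held 49849 different non-control probes, of which 14713 were well above background in all 14 livers and 16933 in none. The 75th percentile of probe signal lay between 51.9 and 104 scanner units per control liver and between 29.0 and 82.0 per EE2 liver. No spot was saturated on any array. The number of arrays limits the precision of every value. The files do not pair the probe IDs with gene names, so probes are given by ID and no gene group was tested.

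The first comparison asked which liver transcripts differ between EE2-exposed and control males. Of 23323 probes tested, 3349 rose and 2679 fell under EE2 relative to each array's 75th percentile, together 25.8% of the tested probes (limma, Benjamini-Hochberg adjusted p under 0.05, 6 control and 8 EE2 livers). The rises reached further than the falls. Among changed probes, 483 rose and 265 fell by at least 4-fold, 196 rose and 49 fell by at least 8-fold, and 97 rose and 13 fell by at least 16-fold. At 64-fold or more there were 48 probes that rose and 0 that fell, and 20 of the 48 rose by at least 1024-fold. These classes depend on how values near background are treated. With normexp background correction 52 probes rose and 23 fell by at least 8-fold, 33 rose and 3 fell by at least 16-fold, 25 rose and 0 fell by at least 64-fold, and 4 rose by at least 1024-fold. The filter on dim probes was also unequal by direction. A probe detected only under EE2 was tested with 6 of the 8 EE2 livers, while one detected only in controls needed all 6. The fold classes were not counted without that filter. The median absolute change of the 6028 changed probes was 1.07 on the log2 scale.

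The probe with the largest rise, CONTIG5344, went from a mean log2 signal of -1.09 ± 2.59 (SD, n = 6) relative to the 75th percentile in control livers to 11.80 ± 0.14 (SD, n = 8) in EE2 livers. Its log2 difference was 12.88 (SE 0.82, limma adjusted p = 4.94e-08), a fold of 7560. On the linear scale its signal ran from 0.038 to 5.88 times the array's 75th percentile in control livers and from 3060 to 3970 times in EE2 livers. It was well above background in 4 of 6 control livers and all 8 EE2 livers, so its fold rests partly on control values at background. With normexp background correction the log2 difference was 10.76, and it was 12.16 without control replicate 3 and 13.61 without control replicate 8. SINGLET_45030 had the next largest rise under the same processing, from -3.69 ± 1.48 (SD, n = 6) to 9.04 ± 0.42 (SD, n = 8), a log2 difference of 12.73 (SE 0.50, limma adjusted p = 1.11e-10). It was well above background on 2 of 8 control arrays, so its fold of 6770 rests largely on control values at background. With normexp background correction the log2 difference was 8.87, and it was then not among the 4 probes that rose by at least 1024-fold. In both probes every EE2 liver lay above every control liver.

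The largest falls under the 75th-percentile scaling were smaller, and their livers varied more. SINGLET_31884 fell by 5.84 on the log2 scale (SE 1.48, limma adjusted p = 0.00993), from 3.64 ± 3.55 (SD, n = 6) in control livers to -2.20 ± 2.67 (SD, n = 8) in EE2 livers. UF_Ppr_AF_103721 fell by 5.83 on the log2 scale (SE 1.52, limma adjusted p = 0.0117), from 3.71 ± 3.70 (SD, n = 6) to -2.12 ± 2.69 (SD, n = 8). Control livers spanned 0.321 to 284 times the 75th percentile for SINGLET_31884, and EE2 livers spanned 0.0434 to 8.78 times, so the groups overlapped. The pair followed each other closely, with a median difference of 0.18 and a largest difference of 0.65 on the log2 scale over the 14 livers. SINGLET_31884 was well above background on all 8 control arrays and 4 EE2 arrays, UF_Ppr_AF_103721 on all 8 control arrays and 3 EE2 arrays. EE2 values were partly at background, so the sizes of both falls rest partly on it, and with normexp background correction the log2 differences were -3.53 for SINGLET_31884 and -3.66 for UF_Ppr_AF_103721, so that neither was among the 3 probes that then fell by at least 16-fold. On slide 1 alone they were -8.05 and -8.18 (limma adjusted p = 0.0317 and 0.0348), and on slide 2 alone -4.47 and -4.32, which did not pass the threshold (limma adjusted p = 0.163 and 0.158). Single livers moved them too, to -4.94 and -4.91 without control replicate 1, -5.22 and -5.20 without control replicate 9, -6.90 and -6.96 without control replicate 14, and -6.61 and -6.59 without EE2 replicate 18.

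**Figure D1:**
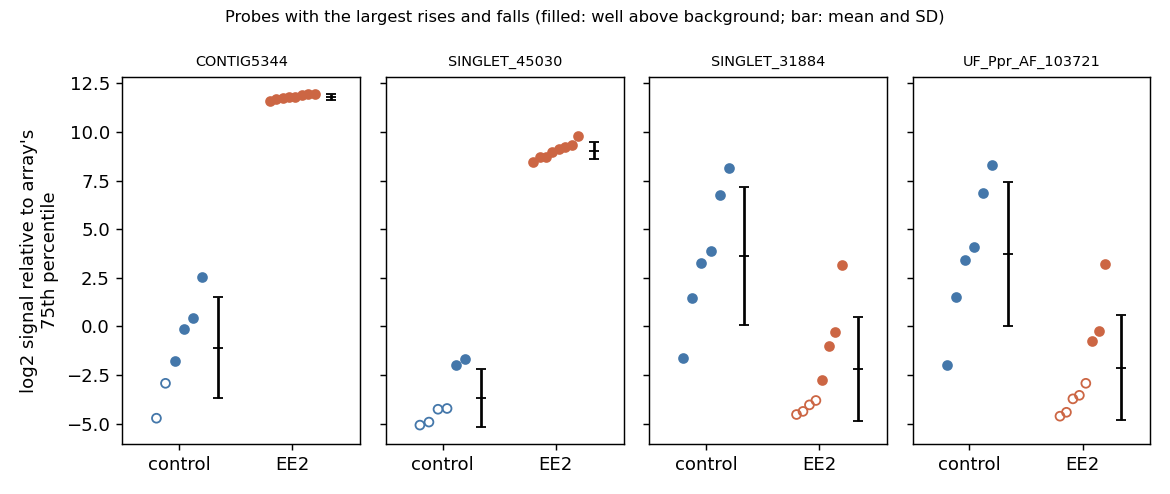
Log2 signal relative to the array's 75th percentile (y axis) for the probes with the largest rises (CONTIG5344, SINGLET_45030) and falls (SINGLET_31884, UF_Ppr_AF_103721) in 6 control and 8 EE2 livers; each point is a liver, filled where the probe was well above background, and the bars are the mean and SD. For both rising probes all 8 EE2 livers sit above all 6 control livers, while for both falling probes the groups overlap.

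All 48 probes raised by at least 64-fold were well above background in each of the 8 EE2 livers, 19 of them in no control liver and 9 in all 6 control livers. For 46 of the 48, every EE2 liver lay above every control liver. The median SD among EE2 livers was 0.588 on the log2 scale for these 48 probes, with a range of 0.136 to 1.24, and 0.501 for all tested probes. Among control livers it was 0.952 for the 48 probes, where many of their values were at background. Together the 48 probes took 4.25% ± 0.68 (SD, n = 8) of all probe signal in EE2 livers and 0.0141% ± 0.0127 (SD, n = 6) in control livers. The exact permutation test over the 3003 splits of the livers gave p = 0.000333 (two-sided, the smallest it can give), on probes that had been picked for their rise in these livers. Of the probes lowered by at least 8-fold, 18 of 49 separated the groups completely, against 165 of 196 of those raised by at least 8-fold. Their median SE was 0.658 on the log2 scale, against 0.433 for those raised. The 196 rises include the 48 of at least 64-fold, while 0 of the 49 falls reached that size. Larger changes separate the groups more readily, so the shares of 18 of 49 and 165 of 196 do not compare changes of equal size. Across the 23323 tested probes the groups did not overlap in 1871, or 8.02%, where chance gives 0.0666%.

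**Figure D2:**
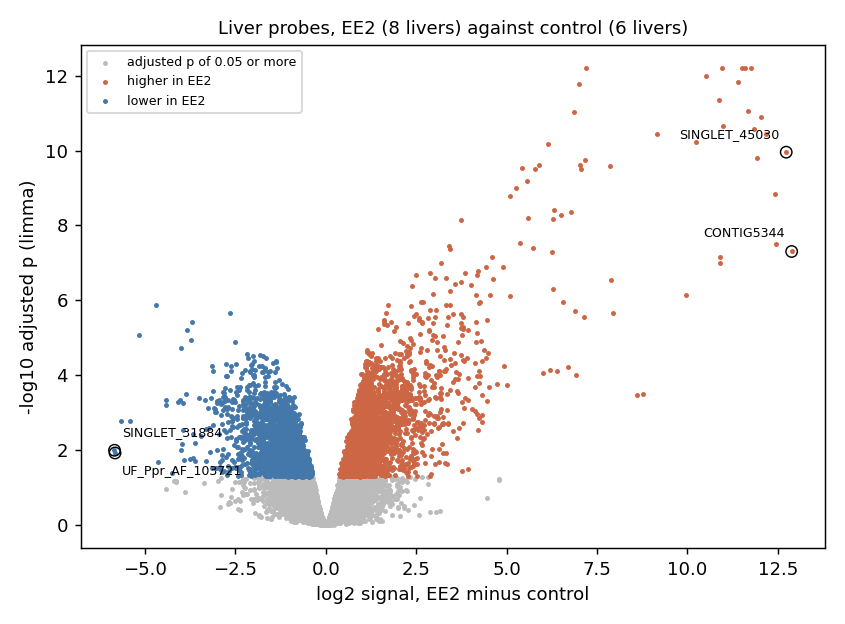
Log2 difference between EE2 and control livers (x axis) against -log10 of the limma adjusted p (y axis) for 23323 probes, coloured where the adjusted p was under 0.05, with 3349 higher and 2679 lower probes. The right arm reaches a log2 difference of 12.88 (CONTIG5344) and the left arm -5.84 (SINGLET_31884).

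Some probes passed from below to above background or the reverse. There were 44 probes well above background in all 8 EE2 livers and in no control liver, and all 44 rose. Another 76 were well above background in all 6 control livers and in no EE2 liver, and 65 of them fell. The first group had a median log2 signal of 0.77 relative to the 75th percentile in EE2 livers, and the second a median of -1.61 in control livers, so the probes lost from detection had been dim. EE2 arrays were also dimmer, with a mean 75th percentile of 58.8 scanner units against 83.1 in controls. Loss of detection through dimmer arrays was not separated from loss of the transcript. Among the 14713 probes detected in all 14 livers, 2595 rose and 1672 fell.

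All 8 exposed fish responded in the same direction. For each liver, the probes changed in a fit on the other 13 livers were taken, and that liver was set against the mean of the other controls. On the probes higher in EE2 the exposed livers stood 1.37 ± 0.27 (SD, n = 8) above the controls on the log2 scale, with a range of 0.93 to 1.68, and the left-out control livers 0.10 ± 0.09 (SD, n = 6), with a range of -0.03 to 0.19. On the probes lower in EE2 the exposed livers stood at -1.13 ± 0.20 (SD, n = 8) and the left-out control livers at -0.18 ± 0.16 (SD, n = 6). For both sets a permutation over all splits of these values gave p = 0.000333 (two-sided, the smallest possible). Each list was picked with the group labels of the other livers and was not picked anew in each split, so that p is not exact. The control mean that a liver was set against came from livers that had picked the list. The left-out control livers accordingly lean in the same direction as the exposed livers. The probe lists differed between livers, from 2892 to 3781 higher probes, so the values do not rank the livers. The first principal component of the tested probes held 33.0% of the variance and separated the groups, from -92.39 to -73.46 in control livers and from 31.12 to 86.07 in EE2 livers.

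The balance of rises and falls depended on the scaling. EE2 arrays had a 75th percentile of 58.8 ± 16.3 (SD, n = 8) scanner units against 83.1 ± 19.5 (SD, n = 6) in controls (exact permutation p = 0.0276, two-sided, 0.0414 after Benjamini-Hochberg over 9 array measures). Some of the 9 measures were defined by probes called in these same livers, which can lower the adjusted p of the other measures. Scaled on the spike-in spots instead, the median tested probe moved by -0.45 on the log2 scale, and 736 probes rose and 3515 fell, so the share of higher calls was 17.3% in place of 55.6%. That scaling moves all probes of an array alike, so it changes which small differences pass.

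The signal of EE2 arrays was concentrated in fewer probes. The 500 brightest probes held 78.2% ± 2.19 (SD, n = 8) of all probe signal in EE2 livers and 72.3% ± 0.782 (SD, n = 6) in controls, a difference of 5.91 percentage points (exact permutation p = 0.000666, two-sided, 0.002 adjusted). The EE2 range of 74.2% to 81.7% lay above the control range of 71.2% to 73.6%. Fewer probes were well above background, 21190 ± 1880 (SD, n = 8) against 24670 ± 2030 (SD, n = 6) per liver (exact permutation p = 0.00766, 0.0138 adjusted). Total signal was 37760000 ± 8860000 scanner units (SD, n = 8) against 39780000 ± 8990000 (SD, n = 6), a difference smaller than the spread between livers (exact permutation p = 0.683, 0.768 adjusted). The spike-in spots differed by -0.11 on the log2 scale, from 13.01 ± 0.27 (SD, n = 6) in controls to 12.90 ± 0.22 (SD, n = 8), also within the spread (exact permutation p = 0.398, 0.512 adjusted).

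**Figure D3:**
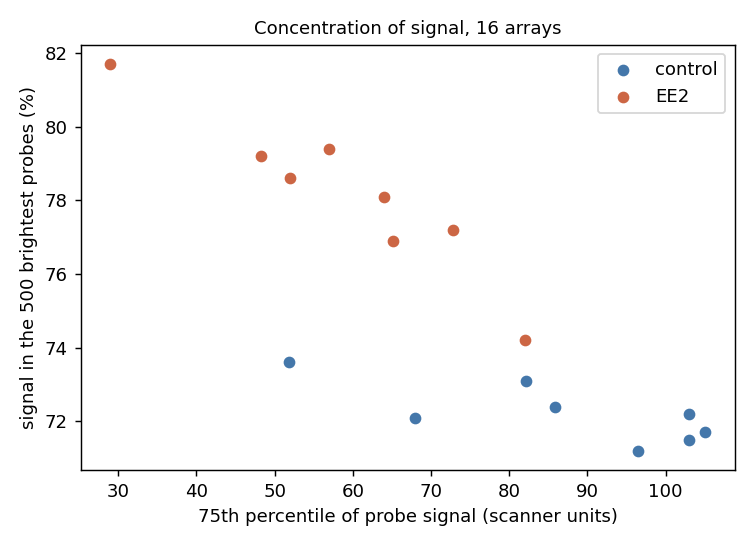
Share of probe signal held by the 500 brightest probes in percent (y axis) against the 75th percentile of probe signal in scanner units (x axis), a point for each of 16 arrays. All 8 EE2 arrays sit between 74.2% and 81.7%, above every control array, and the dimmest EE2 array lies at 29.0 units.

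The probes carry 4 families of IDs, and changes were found in all 4. Of 4795 tested CONTIG probes 27.1% changed, of 10958 tested SINGLET probes 24.3%, of 7422 tested UF_Ppr_AF probes 27.4% and of 148 tested UF_Ppr_AM probes 24.3%. The 48 probes raised by at least 64-fold were 26 SINGLET, 12 CONTIG, 10 UF_Ppr_AF and 0 UF_Ppr_AM probes. Several probes may measure the same transcript, so counts of probes are not counts of genes.

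The next comparison asked how far repeat arrays of a liver differ. The arrays of control replicate 3, both on slide 2, had an SD of log2 differences of 0.269 over the tested probes, and 0.759% of probes differed by over 2-fold. The arrays of control replicate 9, on different slides, had an SD of 0.386, with 2.11% of probes over 2-fold. Arrays of different control livers had SDs of 0.891 to 1.26 on the same slide and 0.934 to 1.20 on different slides, and arrays of different EE2 livers 0.781 to 1.33. A control and an EE2 array differed with SDs of up to 1.56 and a median of 1.35 on the same slide and 1.37 on different slides. The repeat arrays had been counted once because their titles repeat a sample number. They also differed far less than separate livers did, but these are 2 pairs with no test.

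**Figure D4:**
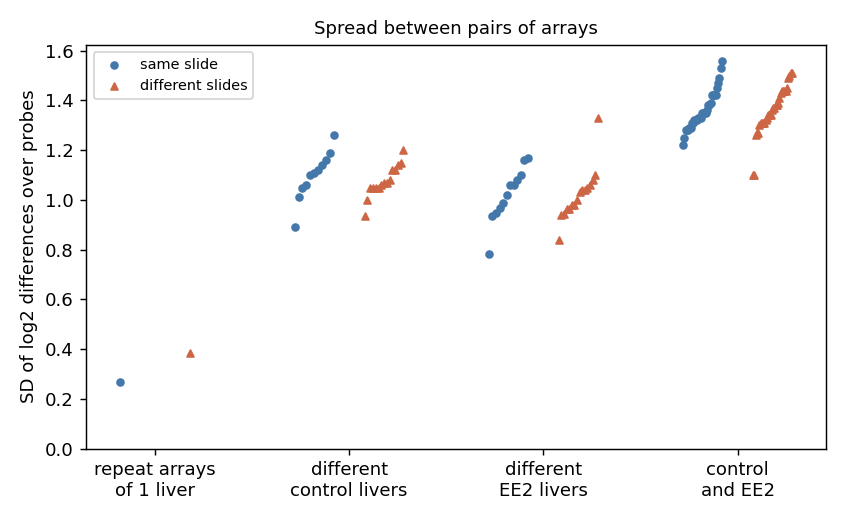
SD of log2 differences over the tested probes (y axis) for each pair of the 16 arrays, by kind of pair (x axis) and by whether the arrays shared a slide (circles) or not (triangles). The repeat arrays lie at 0.269 and 0.386, below all pairs of different livers, whose lowest SD is 0.781.

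The last comparison asked whether the slides differed. With the liver as a random block and group as a term, 3107 of 23254 probes differed between slides (limma adjusted p under 0.05, 16 arrays), with a median absolute log2 difference of 0.501. That fit estimated a correlation of 0.961 between arrays of a liver from 2 livers. Without the block 64 probes differed on the same 16 arrays, and with the block kept at that correlation but the arrays of control replicate 9, the liver measured on both slides, left out, 20 differed. Among the 13 livers measured on 1 slide each, 26 probes differed, and 978 had an unadjusted p under 0.05, or 4.21%. No probe passed for a difference of the EE2 response between slides (limma, 0 probes at adjusted p under 0.05, 1160 at unadjusted p under 0.05). With slide as a term, 5511 probes changed under EE2. Within slide 1 there were 1989 (4 control and 4 EE2 livers) and within slide 2 there were 1317 (3 control and 4 EE2 livers). So that the slides had no liver in common, slide 2 was also fitted without control replicate 9 (2 control and 4 EE2 livers), which gave 370 changed probes. In that fit 1939 of the 1989 probes called on slide 1, or 97.5%, had the same sign, and 236 were called on both, all in the same direction, where independent lists of these lengths would share 18.3.

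Livers of a group also differed from each other. The median SD over tested probes was 0.456 on the log2 scale among control livers and 0.501 among EE2 livers. Some probes had 2 separate states. In 112 probes the sorted values of the 14 livers held a gap of at least 4 on the log2 scale, or 16-fold, with at least 3 livers on each side, a definition chosen after the data were seen. In 41 of them the states followed the groups exactly, and in 62 both states occurred in both groups. For SINGLET_45187, which was singled out after its values were seen as the widest gap among those 62, 7 livers (2 control, 5 EE2) lay between 5.45 and 6.18 and the other 7 between -5.09 and -4.32. In 44 of the 62 probes no liver in the low state was well above background, so the gaps there are not measured folds. None of the 62 was among the 6028 changed probes, as their definition, with both states in both groups, favours. The 2 states were sought among all non-control probes with a value in every liver. Those of the 62 that were well above background in fewer than 6 livers were not tested for EE2 at all.

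**Figure D5:**
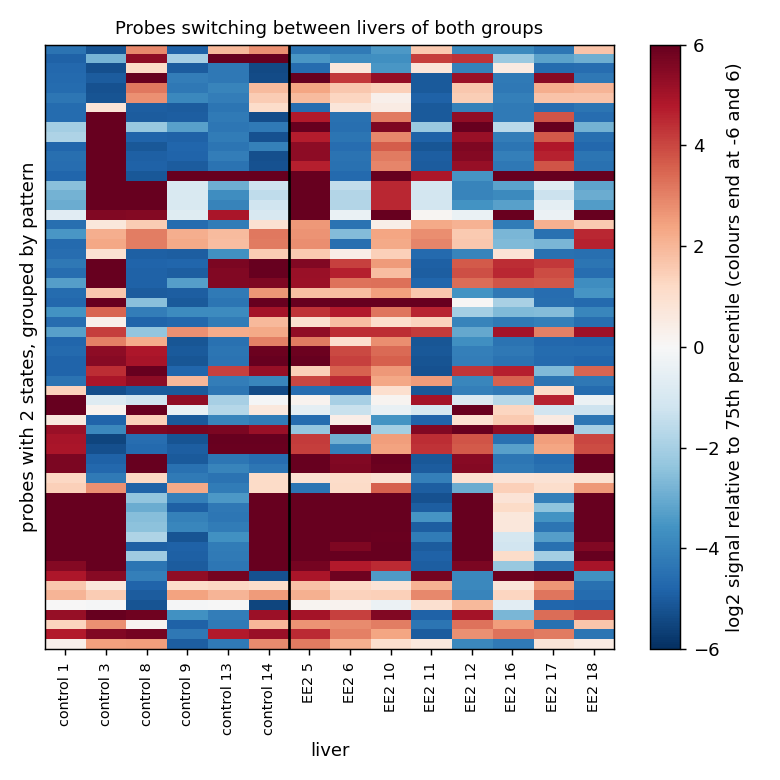
Log2 signal relative to the 75th percentile (colour, ending at -6 and 6) of the 62 probes with both states in both groups (rows) in 14 livers (columns, control left of the line). High and low livers occur in both groups for every probe shown, in 36 different patterns over the livers.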

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

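The tests on array brightness, spike-in spots and the share of signal without the rising probes, and the slide fits other than the 16 arrays with the liver as a block, with the splits of the 13 livers, were chosen only after the results they bear on were seen. The splits of the 14 livers and of the 16 arrays were set down beforehand.

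The share of signal held by the 48 probes raised by at least 64-fold stood apart in EE2 replicate 10, at 5.76% against 3.75% to 4.67% in the other 7 EE2 livers. Its gap to the nearest liver was 0.539 of the group's range. This array was also the dimmest, with a 75th percentile of 29.0. In all, 26 sets of samples were examined in this way, and chance alone marks about 1 in 20.

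The number of probes changed under EE2 was set against other splits of the 14 livers into 6 and 8. Only the real split among 100 gave as many, 1 in all, with 6028 probes against 2368 in the highest other split. That is the smallest share 100 splits can give, and it makes chance an unlikely source of the count. In the highest other split the smaller group held 6 EE2 livers and the larger the remaining 2 with all controls, which is close to the real split turned round. A further 89 of the splits gave no changed probe.

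For the slides, 3 of 100 splits of the 16 arrays, the real split among them, gave as many as the real 3107. The highest other split gave 3497 and the median of the others was 693. The splits did not keep the arrays of a liver together. Those that parted the 2 arrays of control replicate 9 kept a difference between slides within that liver. The counts of the other splits therefore do not show how many probes the fit calls without a slide difference. With only the block removed, 64 probes differed on the same arrays, with 58 in the highest other split and a median of 0. With only the arrays of control replicate 9 left out and the block kept, 20 differed. The count of 3107 thus needed both the block and that liver, and is not a firm measure of slide differences. On the 13 livers measured on 1 slide each, 26 probes differed against at most 6 in the other splits, and the real split was the only 1 of 100 to reach 26. That makes chance an unlikely source of the count but does not exclude it, since the setting was chosen after the results were seen. In that fit 4.21% of probes had an unadjusted p under 0.05, no more than without any slide difference.

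The larger share of signal in the 500 brightest probes of EE2 livers could come from weaker labelling or hybridisation, or from the rising transcripts themselves. Against a dimmer array as the whole cause, 6 EE2 livers were at least as bright at the 75th percentile as the dimmest control, and all 6 had a share above every control, the lowest being 74.2%. The spike-in mean differed by -0.112 on the log2 scale, less than the fall of the 75th percentile. With the probes called higher in the other 13 livers left out, the difference between the groups went from 5.91 to -0.0921 percentage points, but those probes were picked for their rise, so leaving them out lowers the EE2 share whatever raised them. A larger amount of the raised transcripts under EE2 and a labelling step that favours bright probes both stay open.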

How the results depend on the processing

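The count of probes changed under EE2, 6028, stayed within 1.5 times under 27 of 32 alternatives, from 4251 with spike-in scaling to 7567 with the 16 arrays as separate samples. Leaving out each liver in turn gave 5028 to 6839, the highest without EE2 replicate 10, the dimmest array. The count moved to 3379 with a change of at least 2-fold required, 3091 at adjusted p under 0.01, 1989 on slide 1 alone and 1317 on slide 2 alone. It was 370 on slide 2 without control replicate 9, a setting chosen after seeing the data, which leaves 2 control livers. Stricter thresholds lower the count by construction. The fits on 1 slide hold fewer livers, but whether that alone accounts for their lower counts was not tested. Scaling set the balance of directions: 736 higher and 3515 lower on spike-in spots, 3349 and 2679 on the 75th percentile, 3098 and 2820 with quantile normalization, and 3134 and 3153 in the deposited table. Of the 6028 probes, 3188 were also called in the same direction under spike-in scaling, and none was called in the opposite direction under any alternative. The rises of CONTIG5344 (10.76 to 15.64 on the log2 scale) and SINGLET_45030 (8.87 to 13.80) passed under all 31 alternatives in which they were tested. The falls ranged from -8.05 to -2.98 for SINGLET_31884 and from -8.18 to -2.83 for UF_Ppr_AF_103721. SINGLET_31884 lost its call on slide 2, with or without control replicate 9 (adjusted p = 0.163 and 0.413, over all alternatives 0.00293 to 0.413), and UF_Ppr_AF_103721 there (0.158 and 0.404, over all alternatives 0.00291 to 0.404) and at the 0.01 threshold. No fall or rise named turned its sign. Repeat arrays of control replicates 3 and 9 had SDs of 0.257 and 0.369 with quantile normalization, and 0.135 and 0.237 with normexp on median signals, chosen after seeing the files. The slide count was 2557 with quantile normalization and 6289 with normexp (the cause was not tested). In settings chosen after seeing the data it was 64 without the random block, 20 with the block but without the arrays of control replicate 9, and 26 on the 13 livers of 1 slide each, with neither. No paired analysis was possible because the groups share no replicate numbers. Gene lists and the mean of a gene's probes were not run for want of gene names here, nor normexp on mean signals. Signal over background limits the rises: of the 48 probes raised by at least 64-fold, 19 were above background in no control liver and only 9 in all 14 livers. The folds of all but those 9 thus depend wholly or partly on background values.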

Other observations

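The tests in this part were chosen only after the probes with 2 states had been seen.

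Probes that switch between livers of both groups were followed up. The 62 of them had a median gap of 5.53 on the log2 scale and a largest of 9.77, and in 44 of them no liver in the low state was well above background, so these gaps are set partly by background values. The high state occurred in 46.5% of control values and 56.9% of EE2 values. With a gap of 3 there were 118 such probes and with a gap of 5 there were 41.

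Noise of spots or arrays was tested on 56 probes whose states were set by the other 12 livers, and the repeat arrays of control replicates 3 and 9 fell in different states for 1.79% and 0% of them, which argues against it. A single factor ordering the livers, such as the share of another cell type, cannot account for all of the patterns, since 77.1% of pairs of the 36 distinct patterns hold combinations that no single order of the livers allows. A shared factor for part of them stays open: a liver was high in 12 to 54 of the 62 probes, and over the 36 patterns the number high per liver had a variance of 24.6, against 9.81 with states shuffled within groups (permutation p = 6e-04, one-sided). The shuffle took the patterns as independent. Some similar patterns may come from probes of the same transcript, which would make that p too small. Inherited differences between fish in sequence, gene content or expression may also contribute to the 36 patterns, which stays open because no DNA data of the fish were used here.

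A control probe for a synthetic spike-in RNA, ERCC-00062_278, was well above background on all 8 control and all 8 EE2 arrays, at 0.58 ± 0.68 (SD, n = 6) and 0.01 ± 0.78 (SD, n = 8) on the log2 scale relative to the 75th percentile. The other probes of its kind and of the ETG kind were well above background on 0 arrays. Relative to the 75th percentile their mean log2 values were nevertheless all higher in EE2 livers. ERCC-00104_60 went from -4.91 in control to -4.35 in EE2 livers, and ETG09_205211 from -4.92 to -4.36. Differences of probes near background therefore lean towards a rise under this scaling.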
